A study of Mus musculus with 4 samples.

How the data were processed

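ATAC-seq libraries were made from 4 samples of germ cells enriched from female mouse fetal ovaries at E14.5 (embryonic day), 2 from Gata2WT and 2 from Gata2cKO embryos. Groups were taken from the genotype given in the labels. Per the submitters' processing notes, the tools used upstream were Trimmomatic 0.39, Bowtie2 2.3.5.1, SAMtools, Picard 2.23.0, MACS2 2.2.6 and bedtools 2.29.2, with the build GRCm38 (mm10). The notes as used here give no parameters, so the read shift applied for Tn5, the duplicate filter, the fragment or read mode of the peak caller and the use of a list of excluded regions are not given in the sources used here. The processed data were 1 MACS2 narrow peak list per genotype, whose peak names mark it as combined; how the 2 replicates were combined is not given in the sources used here. In a merged alignment the deeper replicate would weigh more.

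The deposited fold enrichment of each peak is the ratio of the pileup at its summit to the local background of the same pool, with 1 fragment added to each, as the authors' peak caller gave it. The deposited −log10 p and −log10 q give the probability of that pileup under the local background, and the deposited score is the whole part of 10 times the −log10 p. The smallest −log10 p in the lists was 3.00, which sets the authors' threshold at p = 0.001. None of these values were scaled between genotypes, so they were used to describe, rank and filter peaks within a list, and values of the same site in both lists stand side by side in the report without a change being read from them. The closing section uses 1 ratio between lists, that of summit pileups relative to each pool's background at strong shared peaks, for a test of depth and enrichment.

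Rows that shared an interval and differed in summit were merged to 1 peak with its highest summit. This took the Gata2WT list from 58367 rows to 49394 peaks on the 19 autosomes and X, and the Gata2cKO list from 52241 rows to 44139 peaks. Depth was taken from the peaks themselves. The fold enrichment and the −log10 p of a peak both depend on its pileup and its local background, so both were solved for together; the pileup came out as a whole number of fragments, within 0.001 in −log10 p, for 99.996% of Gata2WT and 99.9955% of Gata2cKO peaks. The lowest local background of a list is the genome background of its pool. Since the mode of the peak caller is not known, a fragment here is whatever unit was piled up. The background can depend on the length of that unit as well as on depth. The number of reads per sample was not analysed here.

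Peaks of both lists were compared with bedtools 2.31.1, and an overlap of at least 1 bp counted as shared. The level by chance was the overlap after one list had been moved by 100 kb. Genes came from the RefSeq gene table of the same build. That table gives the first and last base of each gene but no strand, transcripts or exons, and no genome sequence was used here. Promoters had been chosen as the unit for location before the data were examined; in their place stand gene ends, within 1 kb of the first or last base of a protein-coding gene. A gene end can thus be the 3′ end, and a promoter that lies inside the span of a gene with several transcripts counts as inside the gene. As a check of the build, 29.2% of Gata2WT peaks and 31.7% of Gata2cKO peaks lay at a gene end, against 7.42% and 7.53% after a move of 100 kb. The planned counts of GATA and other motifs, the split into exons and introns and the GC matching need sequence or transcripts and were not run.

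A peak was given to the gene whose end it reached, and other peaks to the nearest gene end within 100 kb. For each of 19 gene lists fixed before the data were examined, the share of WT-only or cKO-only peaks was placed among 10000 random gene lists of the same size, matched gene by gene on number of peaks (5 bins) and median −log10 q (4 bins). A list was said to lie outside the central 95% below percentile 2.5 or above 97.5. Of the genes written in the lists, 449 were found in the gene table, 4 of them under an older symbol, and 1 was not found. The lists share members, so they are not independent of one another. Named genes followed a rule also fixed in advance. It takes Gata2, a set of 12 germ cell and pluripotency genes, up to 4 members per list and direction with a gene-end peak in 1 list alone, up to 3 members per list and direction with the most distal single-list peaks (at least 2), and the 10 strongest single-list peaks of each genotype; the text gives a part of those it takes.

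Both steps were tested on simulated data. The whole pileup was recovered for 100% of 1844 simulated peaks. Of gene lists of 25 genes with no shift, 5% fell outside the central 95%; a shift of 15 percentage points was found in 88% and one of 30 points in 100%. Alternatives covered the overlap rule, the peak threshold, list length, the gene-end window, the distance to a gene, the matching of random lists and the sequences included. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.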

Results

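Accessible chromatin was mapped by ATAC-seq, in which the Tn5 transposase inserts sequencing adapters into open DNA, in germ cells of female mouse fetal ovaries at E14.5 (embryonic day). The mice were of the C57BL/6J strain. Germ cells were enriched with magnetic beads against SSEA1, a surface sugar antigen of early germ cells, and about 10000 cells went into each library. Embryos with an intact Gata2 (Gata2WT) were set against embryos in which a floxed Gata2 was deleted by Cre recombinase driven from Prdm1, a gene of the germ cell lineage (Gata2cKO). GATA2 is a zinc finger transcription factor that binds GATA motifs and is best known from blood stem cells. The series title names the exit from pluripotency and the start of meiosis as the processes under study. The 4 samples fell into 2 groups of 2, and the authors' processed data analysed here were 1 combined peak list per genotype. The lists therefore carried no replicate error: no test between genotypes was made and no p-value is given. Intervals are 95% Wilson intervals that cover counting error only, and a peak missing from a list fell short of the authors' threshold there, which does not show that the site was closed. The depth behind each list was read from its own values: the genome background was 2.19 fragments in the Gata2WT list and 2.01 in the Gata2cKO list, 8.01% lower, and the median summit pileup was 19 fragments in both.

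At the targeted gene, the Gata2WT list held 5 peaks and the Gata2cKO list held 3. Gata2 lies on chromosome 6 from 88193891 to 88207032 (GRCm38). The peak at the end of the gene, 88193999 to 88194533 with its summit 0.246 kb from the annotated end, was in the Gata2WT list alone, with a fold enrichment of 2.22, a −log10 q of 4.27 and a summit pileup of 45 fragments. A weaker peak outside the gene, 88181121 to 88181597, was also in the Gata2WT list alone, with a −log10 q of 3.31. The other 3 peaks were in both lists: 1 inside the gene at 88197033 to 88198938 in Gata2WT, and 1 on each side of it, at 88189376 to 88190705 and 88209811 to 88210571. At these 3 sites the −log10 q was 22.9, 36.5 and 6.09 in the Gata2WT list and 15.5, 38.7 and 17.1 in the Gata2cKO list. The gene-end peak stood on a local background of 19.8 fragments, well above the genome background, so its low fold enrichment goes with a high pileup. The labels do not say which part of Gata2 was deleted, so these peaks do not check the genotype labels.

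The Gata2WT list was the longer one, and most of what set the lists apart lay in weak peaks. It held 49394 peaks on the autosomes and X against 44139 in the Gata2cKO list, 11.9% more, and covered 32.2 Mb against 28.3 Mb. Of the Gata2WT peaks, 14060 had no overlapping Gata2cKO peak (28.5%, 28.1 to 28.9), and of the Gata2cKO peaks, 8710 had no overlapping Gata2WT peak (19.7%, 19.4 to 20.1). These are called WT-only and cKO-only peaks from here on. When each list was moved by 100 kb, only 4.85% of the Gata2WT peaks and 5.28% of the Gata2cKO peaks met a peak of the other list, against 71.5% and 80.3% in place. The share of single-list peaks dropped steeply with peak strength within each list: for a −log10 q of 2 to 5 it was 52.5% in Gata2WT and 38.9% in Gata2cKO, for 10 to 15 it was 4.82% and 3.05%, and at 30 and over it was 1 of 9995 and 1 of 8648 peaks. Since shared peaks paired nearly 1 to 1, the excess of WT-only over cKO-only peaks follows the 5255 peaks by which the lists differed in length, and equal list lengths bring the counts together by construction (10183 and 10070). Among peaks with a −log10 q of at least 10, 254 of 19547 Gata2WT peaks (1.30%, 1.15 to 1.47) and 145 of 18072 Gata2cKO peaks (0.802%, 0.682 to 0.943) met no peak of the other list.

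**Figure D1:**
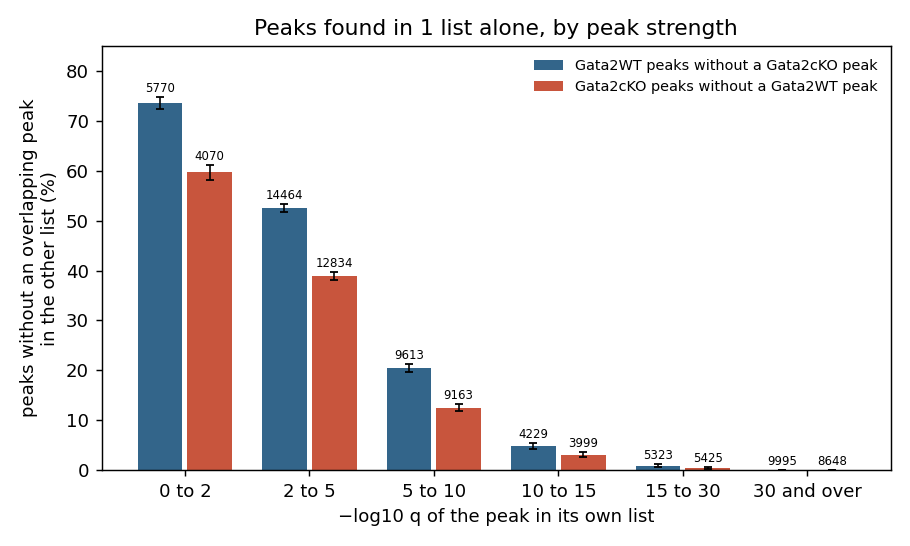
Share of peaks without an overlapping peak in the other list (y axis, percent) by the −log10 q of the peak in its own list (x axis, 6 ranges), for Gata2WT (blue) and Gata2cKO (red) peaks. Error bars are 95% Wilson intervals and the number above each bar is the number of peaks in that range. The share runs from 73.6% and 59.7% below a −log10 q of 2 to 1 peak in each list at 30 and over.

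Single-list peaks lay mostly away from gene ends, in both directions alike. A gene end is used here for the first or last annotated base of a protein-coding gene, with 1 kb on either side, since the gene table held no strand. Gene ends held 37.9% of the shared Gata2WT peaks (37.4 to 38.4) but 7.35% of the WT-only peaks (6.93 to 7.80), and likewise 37.7% of the shared Gata2cKO peaks (37.2 to 38.2) but 7.24% of the cKO-only peaks (6.72 to 7.81). Of the WT-only peaks, 51.6% lay inside genes and 41.0% between genes; of the cKO-only peaks, 52.5% and 40.3%. Part of this split went with strength: among peaks with a −log10 q of 2 to 5, 43.8% of the Gata2WT peaks at gene ends were WT-only against 53.4% elsewhere, and 25.3% of the Gata2cKO peaks at gene ends were cKO-only against 40.5% elsewhere. Of 21631 protein-coding genes, 13595 had a gene-end peak in both lists (62.8%), 496 in Gata2WT alone, 282 in Gata2cKO alone and 7258 in neither; with equal list lengths, 402 had one in Gata2WT alone and 355 in Gata2cKO alone. The median WT-only peak was 359 bp wide with 11 fragments at its summit, against 682 bp and 27 fragments for shared Gata2WT peaks; cKO-only peaks had medians of 333 bp and 11 fragments.

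Nearly all meiotic genes had gene-end peaks in both genotypes. Of the 51 genes of meiotic initiation and prophase, 47 had a gene-end peak in both lists, 3 in neither, 1 in Gata2cKO alone and none in Gata2WT alone. Stra8, which meiotic germ cells switch on in response to retinoic acid, had a shared gene-end peak at 34919641 to 34921232 on chromosome 6, with a −log10 q of 21.3 in Gata2WT and 34.8 in Gata2cKO, and a WT-only peak inside the gene at 34927175 to 34927626 with 4.58. Meiosin, the partner of STRA8 (Bhmg1 in the gene table), had 2 peaks in each list and all were shared, the stronger with a −log10 q of 82.0 and 47.5. Zglp1, a regulator of the oogenic program, Rec8, a meiotic cohesin, and Sycp1 and Sycp3, of the synaptonemal complex, had 1 shared gene-end peak each, with a −log10 q of 42.6 and 36.3 for Zglp1, 88.8 and 60.7 for Rec8, 60.9 and 45.0 for Sycp1, and 42.6 and 29.6 for Sycp3, Gata2WT first. The 1 gene whose gene-end status differed was Stag3, another meiotic cohesin, with a weak gene-end peak in Gata2cKO alone (chromosome 5, 138272485 to 138272845, −log10 q of 1.82). In all, 1 of its 2 Gata2WT peaks was WT-only and 2 of its 3 Gata2cKO peaks were cKO-only, while 1 peak in each list was shared. Away from gene ends, Rec114, Hormad2 and Tex15 had 3, 2 and 2 WT-only peaks against 1, 0 and 0 cKO-only peaks; with equal list lengths these were 3, 2 and 1 against 2, 0 and 0.

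Over all their peaks, the meiotic genes had a low share of cKO-only peaks, whose place among random lists moved with the setting. Of 91 Gata2WT peaks given to them, 18 were WT-only (19.8%), at percentile 58.1 of 10000 random gene lists matched on number and strength of peaks. Of 79 Gata2cKO peaks, 6 were cKO-only (7.59%), at percentile 6.16, within the central 95%; the percentile was 1.345 with matching on number of peaks alone and 0.095 when summits within 250 bp counted as shared, both outside it, and 38.5 with equal list lengths. A percentile describes this pair of lists and is no test over replicates.

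Pluripotency genes supplied 4 gene-end peaks in Gata2WT alone and 1 in Gata2cKO alone, while 24 of the 32 genes had 1 in both lists and 3 in neither. The WT-only gene-end peaks belonged to Dppa5a (chromosome 9, 78367977 to 78368256, −log10 q of 6.21), Tcl1 (2.51), Pou5f1 (2.45) and Dppa4 (1.37), of which that of Dppa4 was lost with equal list lengths. Pou5f1 encodes OCT4, a core pluripotency factor. Of its 2 WT-only peaks, the gene-end one, 35507027 to 35507350 on chromosome 17, lay inside the gene with the summit 1.10 kb from the nearer end. With equal list lengths 1 WT-only peak was left, the gene-end one. The stronger Pou5f1 peak outside the gene, 35503749 to 35504568, was shared, with a −log10 q of 12.2 in Gata2WT and 19.4 in Gata2cKO. At Nanog, another core factor, the direction was the other way: its 5 Gata2WT peaks were all shared, and the Gata2cKO list added a weak gene-end peak at 122707053 to 122707439 on chromosome 6 (1.46) and a peak outside the gene at 122715847 to 122716178 (4.01). Sox2 had 17 Gata2WT peaks, 6 of them WT-only, and 12 Gata2cKO peaks, 1 of them cKO-only. With equal list lengths, 6 were WT-only and 2 cKO-only. The strongest WT-only peak of Sox2 lay 45.3 kb from the gene at 34697490 to 34698151 on chromosome 3, with a −log10 q of 12.4. As a group, 48 of 163 Gata2WT peaks were WT-only (29.4%, percentile 73.8) and 23 of 137 Gata2cKO peaks were cKO-only (16.8%, percentile 23.5), both within the central 95% of random lists.

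All 30 genes of the germ cell identity list had the same gene-end status in both lists: 25 had at least 1 gene-end peak in each and 5 had none in either. Ddx4, the germ cell RNA helicase, had 1 shared gene-end peak with a −log10 q of 37.4 in Gata2WT and 42.1 in Gata2cKO. Dazl, an RNA-binding protein that licenses germ cells for meiosis, had 3 shared peaks and 2 WT-only peaks, the stronger at 50237068 to 50237873 on chromosome 17, 41.9 kb from the gene, with a −log10 q of 12.0; with equal list lengths 1 WT-only peak was left. Prdm1 had 7 WT-only and 3 cKO-only peaks, and Kit, the receptor for stem cell factor, had 6 and 4, but with equal list lengths the counts were 4 and 3 at Prdm1 and 6 and 6 at Kit. Over the list, 31 of 117 Gata2WT peaks were WT-only (26.5%, percentile 54.9) and 23 of 108 Gata2cKO peaks were cKO-only (21.3%, percentile 78.4).

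**Figure D2:**
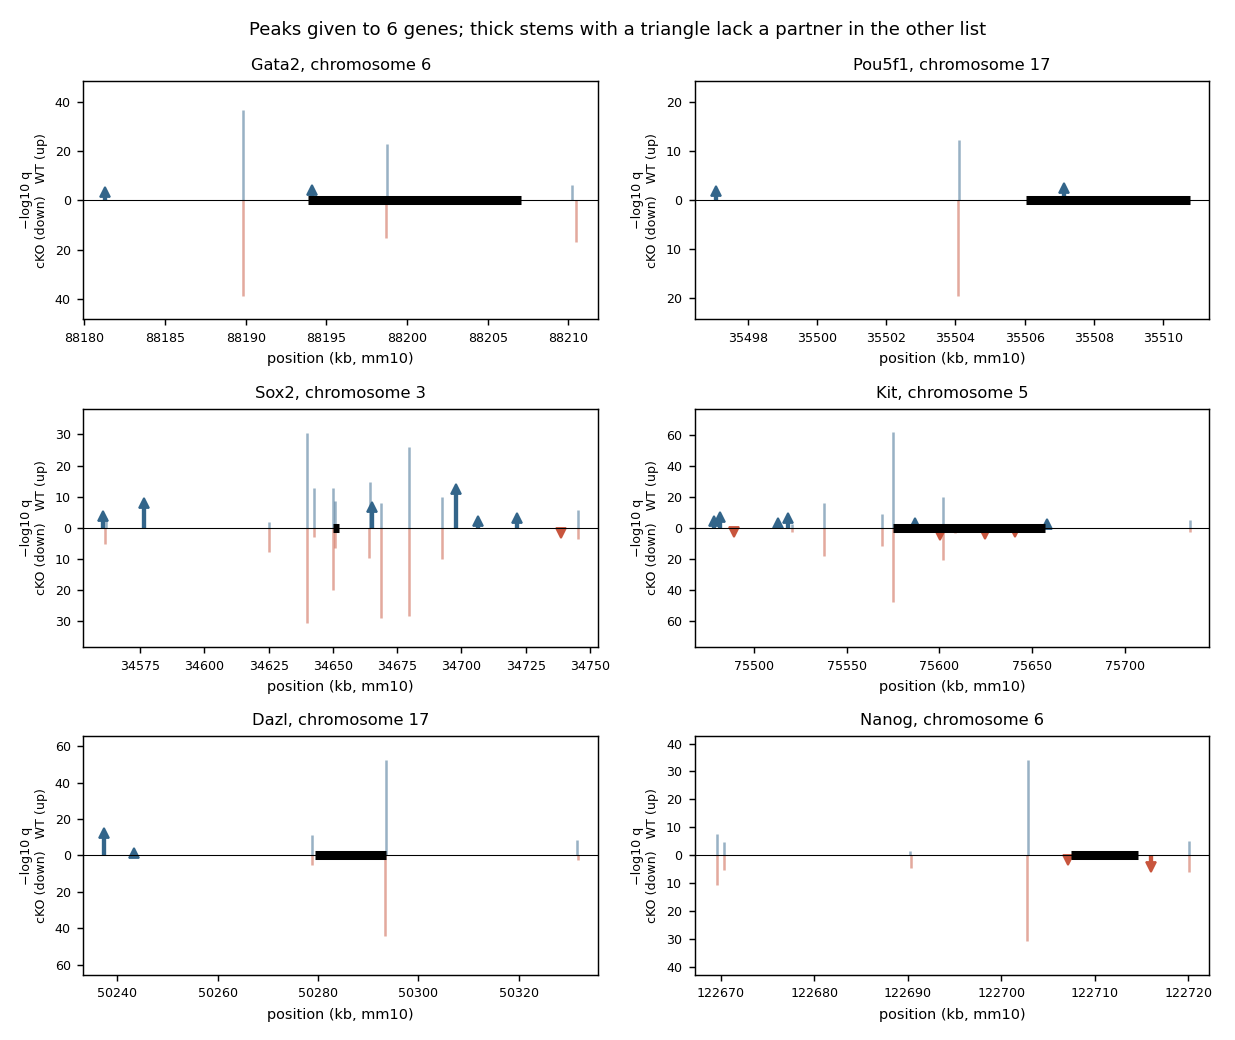
Peaks given to Gata2, Pou5f1, Sox2, Kit, Dazl and Nanog, by position (x axis, kb, mm10) and −log10 q within their own list (y axis, Gata2WT upward in blue, Gata2cKO downward in red); the black bar is the gene. Dark stems with a triangle are peaks with no overlapping peak in the other list, such as the gene-end peak of Gata2 in Gata2WT (4.27) and that of Nanog in Gata2cKO (1.46).

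Oocyte genes and genes of male germ cell fate stayed within the range of random lists in both directions. Ooep, a maternal-effect gene (chromosome 9, 78378201 to 78378542), and Sohlh1, a transcription factor of early oocytes (chromosome 2, 25846409 to 25846955), had gene-end peaks in Gata2WT alone, with a −log10 q of 8.58 and 5.59. Of the 25 oocyte genes, 15 had a gene-end peak in both lists, 8 in neither and none in Gata2cKO alone; 17 of 56 Gata2WT peaks were WT-only (30.4%, percentile 38.4, but 81.3 with gene-end peaks only) and 7 of 46 Gata2cKO peaks were cKO-only (15.2%, percentile 9.97). Among 22 male-fate genes, Piwil4, a piRNA factor of male fetal germ cells, and Ctcfl had gene-end peaks in Gata2cKO alone (2.71 and 1.10), Morc1 and Tdrd7 in Gata2WT alone (both 1.97), 14 genes in both lists and 4 in neither. With equal list lengths the gene-end peaks of Morc1 and Tdrd7 were lost, and 2 genes had one in Gata2cKO alone and 0 in Gata2WT alone. Away from gene ends, Id4 had 3 and Etv4 2 cKO-only peaks, and neither had a WT-only peak. In all, 17 of 73 Gata2WT peaks of the male-fate genes were WT-only (23.3%, percentile 3.36, but 96.8 with gene-end peaks only) and 22 of 78 Gata2cKO peaks were cKO-only (28.2%, percentile 86.7).

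Genes of the retinoic acid, BMP and WNT pathways, signals from ovarian somatic cells to germ cells, stayed within the range of random lists in both directions. Hoxb1, a retinoic acid target, had 3 peaks, all WT-only, with a gene-end peak at 96366360 to 96367248 on chromosome 11 (−log10 q of 3.20). The retinoic acid list had gene-end peaks of 19 of 26 genes in both lists, 1 in Gata2WT alone and 6 in neither, with 39 of 119 Gata2WT peaks WT-only (32.8%, percentile 80.6) and 17 of 98 Gata2cKO peaks cKO-only (17.3%, percentile 21.3). In the BMP list every gene had the same gene-end status in both lists, and 25 of 27 had at least 1 gene-end peak in each. Single members differed in direction: Bmp4 and Bmp7 had 5 WT-only peaks each against 1 and 0 cKO-only peaks, while Smad6, which dampens BMP signals, had 1 WT-only and 7 cKO-only peaks; with equal list lengths these counts were 4 and 1 at Bmp4 and at Bmp7, and 0 and 7 at Smad6. Over the BMP list, 37 of 139 Gata2WT peaks were WT-only (26.6%, percentile 59.2) and 23 of 127 Gata2cKO peaks were cKO-only (18.1%, percentile 46.3). In the WNT list, 22 of 24 genes had gene-end peaks in both lists and Axin1 in Gata2cKO alone (2.49). Ctnnb1 had 4 WT-only and 0 cKO-only peaks and Znrf3 0 and 3, while Tcf7l2 had 8 and 2 but 3 and 4 with equal list lengths. The list's shares were 51 of 165 (30.9%, percentile 42.6) and 29 of 143 (20.3%, percentile 21.7). With gene-end peaks only, the cKO-only percentiles were 88.0 for the retinoic acid list and 94.3 for the WNT list. The WT-only percentile of the BMP list was then 5.27, at a share of 0%, so no lower percentile could be reached.

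The list of GATA factors and their partners had more WT-only peaks than nearly all matched random lists. Of its 107 Gata2WT peaks, 38 were WT-only (35.5%), at percentile 98.9, where the central 95% of random lists ran from 17.9% to 34.3%. Of its 81 Gata2cKO peaks, 10 were cKO-only (12.3%, percentile 5.56). Tcf12, an E protein that pairs with TAL1, had 6 WT-only peaks and 1 cKO-only peak. Erg, an ETS factor that the endothelial list also holds, had 3 and 0. With equal list lengths these were 3 and 1 at Tcf12 and 2 and 1 at Erg. Other members leaned less: Lyl1 had 3 and 2 and Runx1 2 and 2, both unchanged with equal list lengths. At gene ends the 20 genes showed little of this: 12 had a peak in both lists, 7 in neither, and Gata2 itself was the 1 gene with a peak in Gata2WT alone. The excess lay in distal peaks, and the percentile dropped to 50.8 with gene-end peaks only, to 75.6 with peaks within 20 kb of a gene end, to 96.6 when summits within 250 bp counted as shared and to 92.3 when random lists were matched on number of peaks alone.

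Epigenetic regulators and cell cycle genes stayed within the range of random lists in both directions. Of 103 Gata2WT peaks of the epigenetic list, 31 were WT-only (30.1%, percentile 96.0, but 21.9 with gene-end peaks only), among them 5 at Tet1, which oxidises methylated cytosine, and 3 at Dnmt1, the maintenance DNA methyltransferase; the cKO-only count was 1 and 0 at these genes and 17 of 87 over the list (19.5%, percentile 83.1, but 30.9 with gene-end peaks only). Gene-end peaks were in both lists for 29 of its 32 genes and in neither for 3. With gene-end peaks only, its WT-only and cKO-only shares were 0%, so no lower percentile could be reached. Of 112 Gata2cKO peaks of the cell cycle list, 27 were cKO-only (24.1%, percentile 97.3, but 35.3 with gene-end peaks only and 71.4 with peaks within 20 kb of a gene end), 3 of them at Ccnd1, the gene of cyclin D1, which had no WT-only peak; 22 of 104 Gata2WT peaks were WT-only (21.2%, percentile 17.0, but 72.4 with gene-end peaks only). Gene-end peaks were in both lists for 33 of the 35 cell cycle genes. Housekeeping genes, the control list, had 14 WT-only of 73 peaks (19.2%, percentile 35.2) and 8 cKO-only of 69 (11.6%, percentile 25.1), with gene-end peaks in both lists for 27 of 30 genes and at Ywhaz in Gata2WT alone, which was lost with equal list lengths.

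Marker genes of other cells of the fetal ovary leaned to different sides. Markers of supporting cells, the somatic cells around germ cells, had 32 WT-only peaks of 84 (38.1%, percentile 97.6), just past the central range of 19.3% to 38.0%, and 8 cKO-only peaks of 63 (12.7%, percentile 4.06); when summits within 250 bp counted as shared, the cKO-only share was 31.7%, at percentile 75.9. Without Gata4 and Runx1, which the GATA factor list also holds, the WT-only share was 38.4% and its percentile 95.3, within the range. Wt1 had 5 WT-only peaks, Irx3 4 and Rspo1 3, with no cKO-only peak at any of them, and Amhr2 had a gene-end peak in Gata2WT alone (−log10 q of 3.07). Macrophage markers went the other way, with 4 WT-only peaks of 30 (13.3%, percentile 0.475, central range 18.4% to 46.9%) and 10 cKO-only peaks of 36 (27.8%, percentile 75.7); Tyrobp, a myeloid signalling adaptor, had its single peak in Gata2cKO alone (5.01). The WT-only shares of the remaining marker lists were 23.6% for stromal cells (percentile 18.5), 25.7% for endothelial cells (20.7), 40.6% for erythroid cells (94.5), 38.5% for mesothelial cells (91.7) and 23.9% for mesonephric epithelium (11.6). Their cKO-only shares were 13.4% (percentile 7.93), 14.52% (8.40), 13.0% (22.1), 17.2% (34.3) and 15.6% (11.1). Several of these were on the other side of the median when summits within 250 bp counted as shared: the stromal shares were then 38.9% WT-only (75.3) and 35.8% cKO-only (92.5), and the mesonephric cKO-only share was 31.2% (62.3). Of the 38 comparisons over 19 lists, 3 lay outside the central 95%, where chance alone gives 1.9. With gene-end peaks only, 0 did, and the supporting cell and macrophage percentiles were 63.1 and 24.5. Their WT-only shares there were 12.5% and 0%, and at 0% no lower percentile could be reached. The macrophage percentile was also back within the range with equal list lengths (2.64) and with matching on number of peaks alone (4.65).

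**Figure D3:**
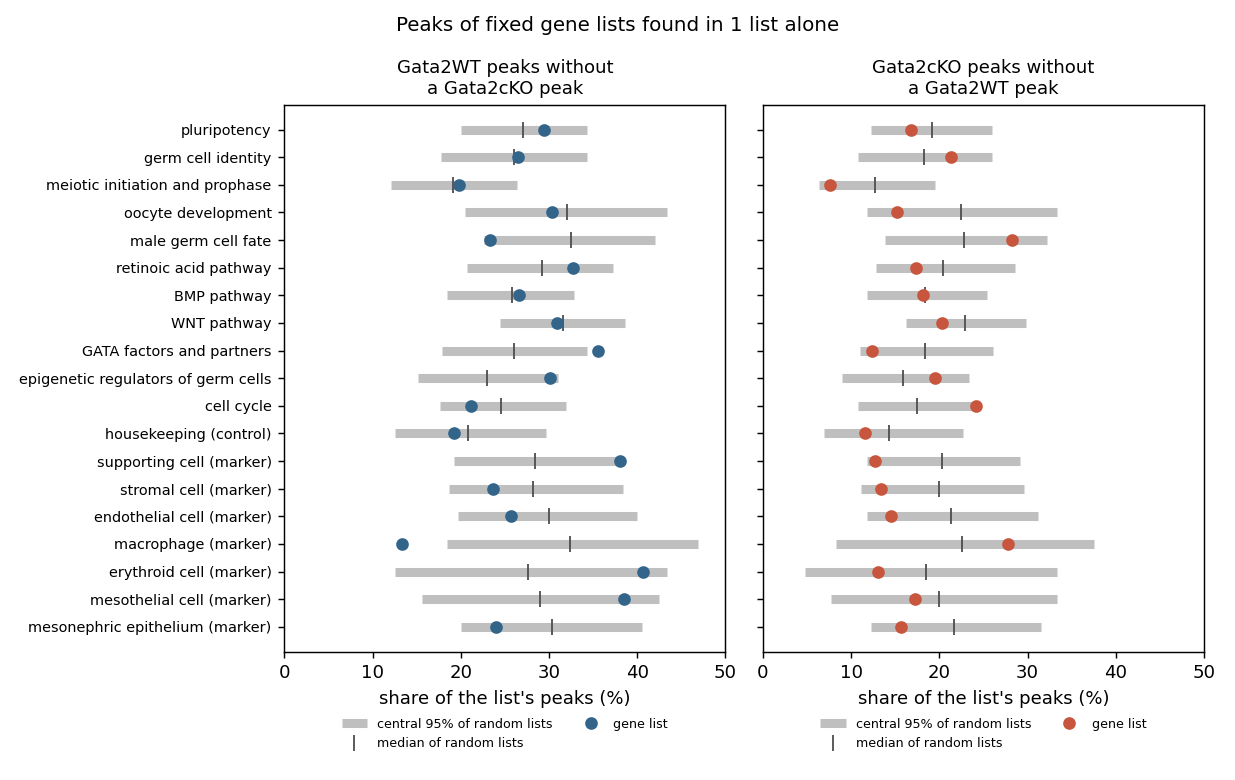
Share of each gene list's peaks found in 1 peak list alone (x axis, percent) for 19 lists (y axis); blue points are WT-only shares of Gata2WT peaks and red points cKO-only shares of Gata2cKO peaks. Grey bars span the central 95% of 10000 matched random lists and ticks mark their median. The points outside the bars are GATA factors and partners (35.5%), supporting cell markers (38.1%) and macrophage markers (13.3%), all on the Gata2WT side.

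The strongest peaks found in 1 list alone were narrow, mostly distal and spread over genes outside the fixed lists. Among Gata2WT peaks, the highest −log10 q was 30.9, at 128369442 to 128370054 on chromosome 3, between genes and 473 kb from the nearest gene end, that of Fam241a. It was followed by peaks near Trim43c (29.9) and inside Fat1, the gene of an atypical cadherin (chromosome 8, 44979145 to 44979719, 29.6), and Cdh4, the gene of R-cadherin (28.6). Of the 10 strongest WT-only peaks, 5 lay inside genes. Those within 1 kb of a gene end numbered 2, at Scaf11 (23.4), also counted among the 5, and at Ino80d (23.2), a subunit gene of the INO80 remodelling complex. The others were nearest to Supt20, Sstr1, Adgrb1 and Shfl. Among Gata2cKO peaks, the highest was 51.2, inside Aida and 2.01 kb from the end of its neighbour Brox, at 183299197 to 183299445 on chromosome 1, with 88 fragments at its summit. Next came peaks inside Slc15a4 (25.6) and Cacna1a, a calcium channel gene (23.5), and peaks nearest to Sdk2 (23.1), Nudt4 (21.7), Ubash3b, Rph3al, Cracr2a, Fn1, the fibronectin gene, and Car6. Of these 10, 6 lay inside genes and 0 within 1 kb of a gene end. Their median width was 503 bp for WT-only and 386.5 bp for cKO-only peaks, against 830 bp and 903 bp for shared peaks of the same strength range.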

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

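The runs of the GATA factor list without Gata2 and of the supporting cell list without GATA factor genes were chosen after the results were seen. No paired analysis was possible because each genotype came as 1 combined list without replicates, and for the same reason no replicate could be left out. Not run, for want of strand, transcripts or sequence, were the window of 2.5 kb upstream to 500 bp downstream and the motif alternatives. WT-only peaks stayed more numerous than cKO-only peaks under every setting but the 10000 highest peaks (1 WT-only, 2 cKO-only), by 10183 to 10070 with equal list lengths. Stricter thresholds leave fewer peaks by construction: at a −log10 q of at least 10 the lists held 19547 and 18072 peaks, with 254 and 145 lacking any partner. With the threshold on both lists, WT-only and cKO-only peaks numbered 5894 and 3953 at 5, and 3253 and 1786 at 10. Gene ends held fewer peaks in a 500 bp window (26.1% of Gata2WT, 28.4% of Gata2cKO, 4.77% of WT-only and 4.55% of cKO-only peaks), more with genes of every kind (36.3%, 38.7%, 14.1% and 13.6%), and 79.3% and 76.9% of the 10000 highest Gata2WT and Gata2cKO peaks; with 1 and 2 single-list peaks left there, their own share was not computed. With gene-end peaks only, 0 gene list comparisons lay outside the central range. Such peaks are fewer, and a list with a share of 0% there could reach no lower percentile. Under the other settings 3 or 4 lay outside, but not the same ones, and the cause was not tested. Supporting cell WT-only shares lay outside in all of these. Beside them stood meiotic (1.345) and GATA factor (1.745) cKO-only shares with matching on number of peaks, meiotic cKO-only (0.095) and macrophage WT-only shares with summits within 250 bp, GATA factor WT-only and stromal cKO-only (1.17) shares with equal list lengths, and macrophage and erythroid (97.55) WT-only and supporting cell cKO-only (0.83) shares within 20 kb. Of 192 percentiles under alternatives, 177 kept their side of the range, 9 came back within it and 6 left it. Most of the 192 belong to comparisons that were within the range in the main analysis. All 9 belong to the 3 that were outside it, the GATA factor, supporting cell and macrophage WT-only shares. The 177 thus say little about how stable those 3 were. In all, 36 lay on the other side of the median from their main value. The supporting cell WT-only percentile was 95.3 without GATA factor genes, at a share of 38.4%. Of 588 peak counts of named genes, 499 stayed within 1.5 times the main count. The median summit of single-list peaks held 11 fragments in both lists, so depth can limit which of them were called.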

Other observations

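Several long genes outside the fixed lists collected single-list peaks mostly in 1 direction. These genes were picked after their values were seen. Epb41l3, the gene of a membrane skeleton protein, had 15 Gata2WT peaks, 10 of them WT-only, against 5 Gata2cKO peaks, 0 of them cKO-only. Dip2b, Fry and Mical3 had 10 WT-only peaks and 1 cKO-only peak each. Tead1, a transcription factor of the Hippo pathway, had 11 and 4. With equal list lengths the WT-only counts were 4 at Epb41l3, 8 at Dip2b and at Fry, 6 at Mical3 and 9 at Tead1. On the Gata2cKO side, Nrf1, a transcription factor of nuclear genes for mitochondria, had 11 peaks, 6 of them cKO-only, against 5 Gata2WT peaks, 0 of them WT-only. Nhsl1 had 8 cKO-only and 2 WT-only peaks, and Sobp 7 and 1.

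The X chromosome had fewer single-list peaks than the autosomes. Of 1102 Gata2WT peaks on X, 22.5% were WT-only (20.1 to 25.1), against 28.6% on the autosomes, which ranged from 24.9% to 32.5%. Of 988 Gata2cKO peaks on X, 12.7% were cKO-only (10.7 to 14.9), against 19.9% on the autosomes, which ranged from 17.0% to 22.0%. Among peaks with a −log10 q of 2 to 5 the WT-only share on X was 52.7% against 52.5% on the autosomes, and the cKO-only share 33.3% (27.3 to 40.0) against 39.0%. The lists of these female samples also held 6 and 4 peaks on Y, all between 90739499 and 90812906. Their source was not tested, so they do not bear on the sex of the samples.

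Of the tests that follow, those of lower depth with lower enrichment, of more non-germ cells and of the GATA factor list without Gata2 were chosen after the results they bear on had been seen. The first pattern is that more Gata2WT peaks lacked a partner than Gata2cKO peaks did. Lower depth of the Gata2cKO pool was tested by thinning the Gata2WT summits to the Gata2cKO background. Of 34323 peaks with a −log10 p of at least 6, 32230 were left (SD 43.3 over 100 thinnings), still above the 31077 Gata2cKO peaks. Depth alone thus leaves 35.5% of the difference in the number of such peaks. The Gata2WT summits were then also thinned by the lower summit pileup of the Gata2cKO pool, relative to background. That ratio was 0.895 at 14413 strong shared peaks. This left 28210 peaks (SD 50.2), below the 31077 of the Gata2cKO list. The ratio of strong peaks was applied to weak ones too, and to the background fragments within each pileup. The count overshot the Gata2cKO number, so how much of the difference lower depth with lower enrichment accounts for cannot be told. A lower accessibility at shared sites without GATA2 would give the same ratio, and stays open as untested. The thinning kept each Gata2WT summit in place and let no weaker site rise, so its counts may be too low. Peaks lacking a partner were not recounted after thinning, so these values bear on peak numbers and only indirectly on the pattern.

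The second pattern is the strong single-list peaks, 254 WT-only and 145 cKO-only at a −log10 q of at least 10. Had these sites been equally open in both pools, counting at the other pool's depth would have missed 6.02 Gata2WT and 0.967 Gata2cKO peaks. At equal enrichment, counting noise could thus account for few of them. That count leaves out the lower summit pileup of the Gata2cKO pool at strong shared peaks, a ratio of 0.895. It could raise the number of Gata2WT peaks missed, and its part there was not tested. For the cKO-only peaks this median ratio points the other way, so it would not add to the number missed. Spread between embryos or pools, mapping in repeats and a difference by genotype all stay open, since the lists carry no replicates.

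The third pattern is the high WT-only share at GATA factors and partners and at supporting cell markers. The peaks at Gata2 alone are not the source, as the GATA factor list stayed at percentile 98.4 without Gata2. Gata2 held 2 of the 38 WT-only peaks of that list, so leaving it out could move the share little. No other gene, such as Tcf12 with 6 WT-only peaks, was left out of it. Without Gata4 and Runx1, which both lists hold, the supporting cell share was 38.4% but its percentile 95.3. More non-germ cells of every kind in the Gata2WT pool would raise the WT-only share of all marker lists. Those of supporting, erythroid and mesothelial cells, 3 of the 7, lay above the median of their random lists. The supporting cell list is itself part of the pattern, and the mesothelial list shares Wt1 with it. Macrophage markers lay at percentile 0.475. This explanation stays open, since that percentile was 2.64 with equal list lengths and 4.65 with matching on number of peaks alone. With gene-end peaks only it was 24.5, but the share was 0% there. No lower percentile could be reached, so that setting cannot decide. More supporting cells alone, which the bead enrichment should deplete, may underlie the shares. A loss, without GATA2, of distal sites at genes of the list of GATA factors and partners may do so too. Neither was tested. Chance also stays open, with 3 of 38 comparisons outside a range where 1.9 would fall.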
